A study of Anas platyrhynchos with 6 samples.

How the data were processed

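RNA sequencing libraries were made from the ovarian tissue of 6 ducks at 71 weeks, 3 labelled with a high egg number (HEN) and 3 with a low egg number (LEN). Per the labels' protocols, total RNA was extracted with TRIzol from frozen ovarian tissue and libraries were prepared with standard Illumina reagents. The groups and replicate numbers were taken from the sample labels. The aligner, the counting tool and the genome build were not given in the sources used here. The ducks are separate animals of a full-sib family, and no label gave a sequencing batch, so that batch effects were not analysed.

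The authors deposited a table of FPKM values, as its name states, with 17191 rows of Ensembl duck transcripts and their gene, scaffold, start, end and biotype. The rows held 17169 transcripts of 16450 genes on 2600 scaffolds, because 22 transcripts were listed again with the same values and were used as 1 row. Coordinates are those of the deposited table. Symbols came from the table for 11101 transcripts and, through their Entrez identifiers, from a RefSeq gene table of another assembly (IASCAAS_PekinDuck_T2T) for 707 more, while 5361 stayed unnamed. Of 8292 rows with an Entrez identifier, 7651 matched that table. Because 1842 transcripts overlap the position of another gene and strandedness was not stated, fragments of such genes cannot be told apart.

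The depth of each library was inferred from the steps between values of short noncoding genes. For 280 such genes, 100% of 875 values under 200 fragments were whole multiples within 0.02 of a fragment. The inferred depths were about 18994499, 18756660 and 18213744 fragments for HEN replicates 1, 2 and 3 and 19228733, 19831761 and 18331418 for LEN replicates 1, 2 and 3. FPKM of 1 on a transcript of 1 kb equalled 18.2 to 19.8 fragments. PCR copies cannot be separated, so limits derived from fragments cover counting error only.

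Values were analysed as deposited, as log2(FPKM + 1), which understates the change of low genes. Transcripts with a mean of at least 1 FPKM over the 6 libraries were kept (13328). HEN and LEN were compared with limma 3.58.1 in R 4.3.3 (moderated test with a trend, Benjamini-Hochberg adjustment, threshold 0.05), with group as the only term. No FPKM value was passed to a count test. Correlations between libraries are Pearson's r across genes, which are not independent replicates. An exact permutation test of 3 against 3 ducks cannot give a two-sided p below 0.1.

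Before the data were examined, 28 gene lists, the design, the alternatives and the rule for named genes were fixed. The lists covered the theme of the series title (integrin beta and alpha subunits, actin cytoskeleton, focal adhesion and extracellular matrix), ovarian and general functions, and markers of cell types that ovarian tissue could hold. Every list member counted as measured passed the filter in these ovaries, and some members are shared between lists, most in the theca and stroma (9 of 13), granulosa (7 of 16), steroidogenesis (5 of 17) and TGF-beta (5 of 29) lists. Lists were tested with camera (two-sided, preset correlation 0.01, adjusted over 28 lists), and again with an estimated correlation and with fry's test of 1 direction. Named were 10 genes per direction with no overlap between groups, all integrin beta genes, and up to 4 members with the smallest unadjusted p from each other list, 128 in all. As no gene passed, the 10 per direction were taken by the smallest unadjusted p, leaving out symbols found on several rows. Of the 128, 16 overlap another gene's position and 4 have several rows for their symbol. Some of the named genes are not reported here. Several of the 128 are members of gene families whose fragments the unstated counting could have split, such as ribosomal proteins.

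The alternatives were pseudocounts of 0.1 and 0.01, no filter or a mean of at least 5 FPKM, scaling to TPM, to the upper quartile or by trimmed means, quantile normalization, limma with robust variance, without trend or with arrayWeights, the replicate number as a block, values summed per symbol, other thresholds, and leaving out each library in turn. Leaving out HEN replicates 2 and 3 together, using protein-coding rows alone and fry's mixed test of changes in either direction were added after the data were seen. Without that pair of libraries the remaining HEN library stands alone, so p values there measure no spread between HEN ducks. The trimmed mean factors used trims of 30% on log ratios and 5% on mean levels.

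The limma and camera steps were tested on simulated data of 13328 genes with 50 changed genes per fold and the other members of the WNT list (32) raised by 0.5 log2 units in HEN. With the spread of the LEN libraries, 4%, 36%, 62% and 88% of genes changed by 1.5, 2, 4 and 8 fold were recovered, with 2 false calls among 13096 unchanged genes. With the pooled spread of both groups the shares were 0%, 0%, 40% and 76%, with 0 false calls among 13096 (5.13% had an unadjusted p under 0.05). Camera called the raised list in both (adjusted p = 5.82e-12 and 3.84e-07) and 0 other lists. Simulated genes varied independently of each other, so this does not show how the preset correlation performs on the real lists. There the estimated correlation between members ran from -0.049 (granulosa) to 0.858 (cell cycle). Intervals came from 10000 bootstrap draws of list members and permutation p values from 100000 resamples, with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.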

Results

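Transcript levels were measured by RNA sequencing of ovarian tissue from 6 ducks (Anas platyrhynchos) at 71 weeks of age, all from a full-sib family. The ducks formed 2 groups of 3, with a high egg number (HEN) or a low egg number (LEN), and each duck gave 1 library. Values were FPKM, fragment counts scaled to transcript length and library size, for 17169 Ensembl duck transcripts. The steps between low values corresponded to 18213744 to 19831761 fragments per library, so that 3 fragments on a transcript of 1 kb equalled 0.151 to 0.165 FPKM. Between 14722 and 15559 transcripts had a value above 0 in a library.

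The comparison addressed which ovarian transcripts differ between ducks of high and low egg number. Relative to the LEN mean, medians of the extracellular matrix and interferon lists were higher in all 3 HEN ovaries than in any LEN ovary. Each LEN ovary is part of that mean, which narrows the LEN range. For the matrix list no comparison free of this was made, so its separation is uncertain. The HEN levels of the homeobox genes GSX2 and DLX6 lay below all LEN levels. SPARC, a collagen-binding matrix protein, was at 944 ± 99.9 FPKM in HEN and 467 ± 11.8 FPKM in LEN (SD, n = 3 per group), a difference of 1.01 ± 0.20 (SE) on the log2(FPKM + 1) scale. The homeobox gene GSX2 was at 2.84, 0.18 and 0 FPKM in HEN replicates 1, 2 and 3 and at 20.8, 8.998 and 17.4 FPKM in LEN replicates 1, 2 and 3, a difference of -3.27 ± 0.58 (SE).

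None of these differences passed the test across all genes. limma found 0 of 13328 transcripts at an adjusted p under 0.05, and the smallest adjusted p was 0.11. At an unadjusted p under 0.05 there were 2929 transcripts, 680 with higher and 2249 with lower HEN levels. Without HEN replicate 1, limma called 6501 transcripts, 1569 higher and 4932 lower in HEN, and with arrayWeights it called 7922, 2194 higher and 5728 lower. Those weights were 0.114, 1.20 and 1.97 for HEN replicates 1, 2 and 3 and 5.62, 1.19 and 0.556 for LEN replicates 1, 2 and 3. Without HEN replicates 2 and 3, an alternative chosen after seeing the data, it called 1. The groups did not overlap for 2703 transcripts, which was 20.3% where chance gives 10%, with HEN above LEN for 922 and below for 1781. That 10% is a mean over splits, and transcripts vary together, so a share above it does not by itself show a group difference. The median log2 difference over all transcripts was -0.24 in the values as deposited, against 0.01 after upper quartile scaling, -0.01 after scaling by trimmed means and 0.07 after quantile normalization.

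The 10 genes with a symbol on 1 row of the table that had the smallest unadjusted p among those higher in all HEN ovaries included IL4I1, ASS1, GEM, SPARC, C1S, COL6A1, LINGO1, ZC3HAV1 and ERAP1. IL4I1 (ENSAPLG00000016019, scaffold KB742989.1 from 38108 to 41560), an amino acid oxidase of immune cells, was at 10.7 ± 2.44 FPKM in HEN and 0.974 ± 0.415 FPKM in LEN (SD, n = 3 per group), a difference of 2.57 ± 0.31 (SE). ASS1, the urea cycle enzyme argininosuccinate synthase, differed by 2.20 ± 0.33 (SE), although its position overlaps another gene. The GTP-binding protein GEM differed by 2.02 ± 0.37 (SE), the complement protease C1S by 1.52 ± 0.30 (SE) and the peptidase ERAP1, which trims antigenic peptides, by 1.47 ± 0.31 (SE). Each of the 10 had an adjusted p of 0.226 in limma. The 10 genes chosen likewise among those lower in all HEN ovaries included GSX2, SLC6A20, DUSP26, DLX6, AQP11, AVPR1B, MRPL22, CA10 and CLDN19, also with an adjusted p of 0.226 each. DUSP26, a protein phosphatase, was at 16.5 ± 7.54 FPKM in HEN and 63.9 ± 17.6 FPKM in LEN (SD, n = 3 per group), a difference of -1.94 ± 0.37 (SE). The homeobox gene DLX6 differed by -2.33 ± 0.46 (SE), with HEN replicate 1 at 1.30 FPKM and the other HEN libraries at 0 FPKM. MRPL22, a mitochondrial ribosomal protein gene whose position overlaps another gene, differed by -1.79 ± 0.37 (SE).

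The HEN libraries were not alike. Over the transcripts tested, the correlation across genes of log2(FPKM + 1) was 0.965 between HEN replicates 2 and 3, but 0.748 and 0.752 between each of these and HEN replicate 1. HEN replicate 1 correlated at 0.933 to 0.964 with the LEN libraries, which correlated at 0.933 to 0.959 with each other, while HEN replicates 2 and 3 correlated at 0.634 to 0.779 with LEN. The 10 highest transcripts took 10.6% and 13.2% of all FPKM in HEN replicates 2 and 3 and 4.38% to 5.28% in the other libraries. The median SD per gene was 0.47 on the log2 scale within HEN and 0.28 within LEN.

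**Figure D1:**
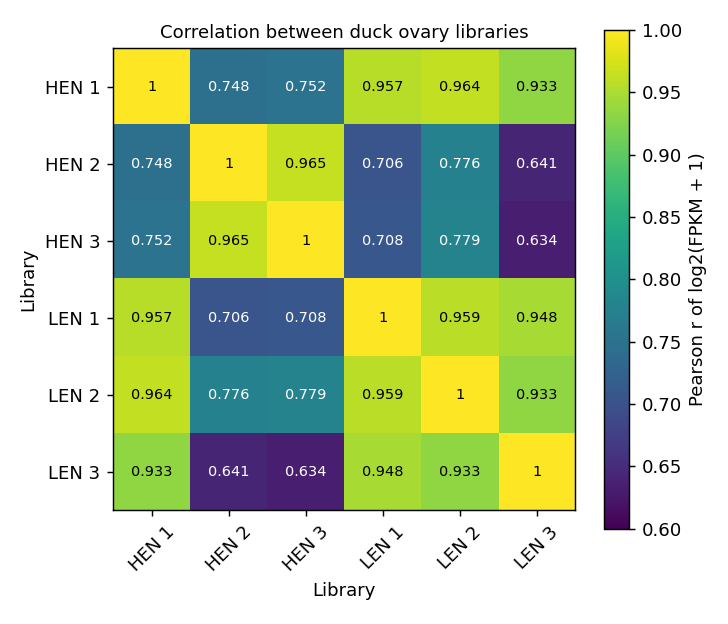
Pearson correlation across genes of log2(FPKM + 1) between each pair of the 6 ovary libraries, coloured by value. HEN replicates 2 and 3 correlate at 0.965 with each other and at 0.779 or less with the LEN libraries, whereas HEN replicate 1 correlates at 0.933 to 0.964 with LEN.

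The series title names integrin beta genes and actin cytoskeleton regulation. Integrin beta subunits pair with alpha subunits to form receptors for extracellular matrix. Of 7 measured subunits, 5 had a higher mean in HEN and 2 a lower mean. ITGB5 (ENSAPLG00000007419, scaffold KB742929.1 from 4654529 to 4697595) was at 32.9, 162 and 149.9 FPKM in HEN replicates 1, 2 and 3, against 25.9, 24.4 and 21.9 FPKM in LEN replicates 1, 2 and 3, a difference of 1.91 ± 0.59 (SE). ITGB3, named through its Entrez identifier, was at 6.60 ± 3.94 FPKM in HEN and 0.921 ± 0.678 FPKM in LEN (SD, n = 3 per group). ITGB2, the leukocyte subunit, was at 44.99 ± 35.5 and 11.5 ± 4.99 FPKM (SD, n = 3 per group). ITGB1, the most abundant subunit, was at 91.3, 208 and 161 FPKM in HEN and 83.6, 105 and 56.2 FPKM in LEN, a difference of 0.87 ± 0.37 (SE). ITGB8, whose position overlaps another gene, differed by 0.84 ± 0.47, ITGB4 by -0.61 ± 0.37 and ITGB6 by -1.02 ± 0.48 (SE).

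As a list, the integrin beta subunits shifted upward relative to all other genes in limma's camera test with a preset correlation (median log2 difference 0.87, adjusted p = 0.012 over 28 lists), with adjusted p = 0.453 with an estimated correlation. No subunit passed over all genes tested, and 0 of 7 passed adjusted over the list alone, with 3 of 7 at an unadjusted p under 0.05. Without HEN replicate 1, 4 subunits passed as higher and 1 as lower, where 1569 and 4932 of all 13328 transcripts did so. The counts given below for other lists in that setting stand against the same share. Without HEN replicates 2 and 3 the list's median was 0.25 (adjusted p = 0.1). After scaling by the upper quartile, trimmed means or quantiles its medians were 1.15, 1.13 and 1.14, larger than as deposited, although the adjusted p was 0.0692, 0.0631 and 0.0749. The list's median relative to the LEN mean was 0.25 in HEN replicate 1, 1.42 and 1.02 in replicates 2 and 3, and between -0.36 and 0.40 in LEN. The integrin and actin lists, and the focal adhesion list, follow the theme of the series title, which the study chose on these samples, so that their counts are not independent evidence of a direction.

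**Figure D2:**
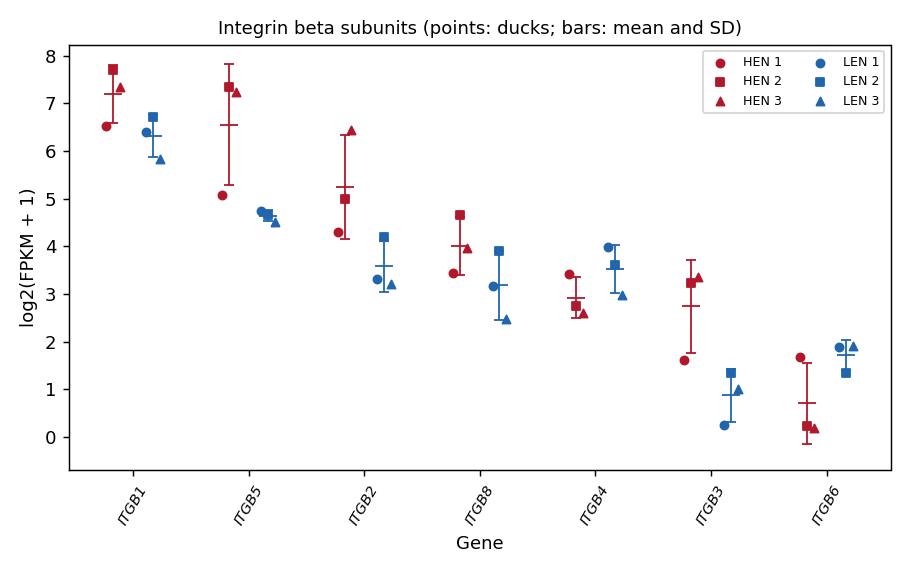
Levels on the log2(FPKM + 1) scale of the 7 measured integrin beta genes, with 1 point per ovary library and the mean and SD of each group. ITGB5, ITGB2 and ITGB3 have all HEN points above all LEN points, whereas the groups overlap for ITGB1, ITGB4, ITGB6 and ITGB8.

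The actin cytoskeleton list held 95 measured genes, of which 61 had a higher and 34 a lower mean in HEN. ACTN1, an actin crosslinker, was at 93.2, 170.4 and 139 FPKM in HEN and 71.9, 85.7 and 53.4 FPKM in LEN, a difference of 0.90 ± 0.30 (SE). PIP5K1B, a phosphoinositide kinase, differed by -1.11 ± 0.38 (SE) and the G protein subunit gene GNG12 by -0.96 ± 0.34 (SE). The list shifted upward in camera (median 0.15, adjusted p = 4.18e-05), with adjusted p = 0.453 with an estimated correlation. Its median relative to the LEN mean was 0.104, 0.089 and 0.223 in HEN replicates 1, 2 and 3. In LEN replicates 1, 2 and 3 it was 0.043, 0.155 and -0.174, so the groups overlapped. No member passed over all genes or adjusted over the list alone, and 12 higher and 4 lower members had an unadjusted p under 0.05. Without HEN replicate 1, 28 passed as higher and 13 as lower, and without HEN replicates 2 and 3 the list's median was 0.10 (adjusted p = 0.0544). The actin list's median was 0.24 without LEN replicate 2, and 0.42, 0.39 and 0.36 after scaling by the upper quartile, trimmed means or quantiles. Integrin alpha subunits did not pass (8 genes, median 0.41, or 0.26 without HEN replicate 2 and 0.79 after quantile normalization, adjusted p = 0.107), with ITGAV, whose position overlaps another gene, at 1.36 ± 0.59 and ITGA8 at 1.49 ± 0.65 (SE). That list passed as higher without HEN replicate 1 (median 0.68, adjusted p = 0.0219), where 4 members passed as higher and 2 as lower, and with arrayWeights (median 0.62, adjusted p = 0.0342), and its direction was downward without HEN replicates 2 and 3 (median -0.09, adjusted p = 0.48).

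Of 50 focal adhesion and extracellular matrix genes, 39 had a higher mean in HEN. The collagen gene COL3A1 was at 424, 464 and 586 FPKM in HEN replicates 1, 2 and 3 and at 148, 197 and 59.2 FPKM in LEN replicates 1, 2 and 3, a difference of 2.01 ± 0.44 (SE). COL6A1 (scaffold KB743649.1 from 121044 to 141183) differed by 1.70 ± 0.34 (SE) and COL6A2, which has several transcripts in the table, by 1.19 ± 0.21 (SE). The list shifted upward in camera (median 0.94, adjusted p = 2.4e-11), with adjusted p = 0.453 with an estimated correlation. No member passed over all genes and 5 passed adjusted over the list alone, while 24 higher and 2 lower members had an unadjusted p under 0.05. Unlike the integrin beta list, this list had a median in HEN replicate 1 (0.41) above those of all LEN libraries (-0.36 to 0.27). Each LEN library is set there against a mean that includes itself, which narrows the LEN range, so this separation is uncertain. Without HEN replicate 1, 24 members passed as higher and 6 as lower, and on leaving out HEN replicates 2 and 3 the list's median was 0.41.

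The lists of stroma, smooth muscle and endothelial markers had positive medians. Among 13 theca and stroma markers, 9 of which are also in another list, the median difference was 0.56 and the mean 0.051 (camera adjusted p = 0.00111), with adjusted p = 0.453 with an estimated correlation, and 3 passed adjusted over the list alone. In that list TNC differed by 2.17 ± 0.56 and the stromal transcription factor TCF21 by 0.89 ± 0.24 (SE), while the aromatase gene CYP19A1 differed by -2.26 ± 0.90 (SE). On leaving out HEN replicate 1, 4 of the 13 passed as higher and 3 as lower, and on leaving out LEN replicate 3 the median was 0.26 (adjusted p = 0.00227). The 15 smooth muscle markers had a median of 0.63 (camera adjusted p = 4.21e-04), with adjusted p = 0.453 with an estimated correlation, and TPM1 and KCNMB1 differed by 0.77 ± 0.25 and 0.74 ± 0.24 (SE). The smooth muscle median was 0.38 without LEN replicate 3 (adjusted p = 0.00153) and 0.28 with arrayWeights (adjusted p = 0.0439). The 19 vascular endothelial markers had a median of 0.62 (camera adjusted p = 2.38e-06), with adjusted p = 0.453 with an estimated correlation. LYVE1, a hyaluronan receptor of lymphatic endothelium, was at 16.99, 80.2 and 40.5 FPKM in HEN and 9.41, 9.12 and 9.93 FPKM in LEN. No smooth muscle or endothelial marker passed adjusted over the list alone, and 5 in each list had an unadjusted p under 0.05. Without HEN replicates 2 and 3 the endothelial median was 0.23, against 0.585 for theca and stroma and 0.69 for smooth muscle markers. The endothelial median was 0.98 after quantile normalization.

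Of 18 interferon response genes, 13 had a higher mean in HEN. The antiviral protein gene ZC3HAV1 was at 35.4, 57.5 and 40.9 FPKM in HEN and 17.5, 20.2 and 17.6 FPKM in LEN, a difference of 1.20 ± 0.25 (SE). The ubiquitin ligase gene TRIM25 and B2M, the light chain of class I histocompatibility molecules, each differed by 0.93 with SE of 0.24 and 0.27. The list shifted upward in camera (median 0.56, adjusted p = 3.46e-04), with adjusted p = 0.453 with an estimated correlation. No member passed over all genes and 4 passed adjusted over the list alone. On leaving out HEN replicate 1, 4 members passed as higher and 4 as lower and the list's adjusted p was 0.0465. The list's median relative to the LEN mean was 0.83, 0.29 and 0.43 in HEN replicates 1, 2 and 3 and -0.054 to -0.024 in LEN. Leukocyte markers (26 genes, median 0.56) also shifted upward in camera (adjusted p = 9.9e-04), with adjusted p = 0.659 with an estimated correlation, and 3 passed adjusted over the list alone. Their medians were -0.34 in HEN replicate 1 and 0.99 and 1.20 in replicates 2 and 3, and without these 2 libraries the direction was downward (median -0.34, adjusted p = 0.0715). The leukocyte list's median was 0.99, 0.30 and 1.02 without HEN replicate 1, HEN replicate 3 or LEN replicate 2, 1.03 with a filter at a mean of 5 FPKM and 1.10 with arrayWeights, and its call held in each. The macrophage genes MARCO and C1QB differed by 2.09 ± 0.48 and 1.46 ± 0.33 (SE), whereas the B cell factor PAX5 differed by -1.56 ± 0.35 (SE). Erythrocyte markers (8 genes, median 0.50) did not pass (adjusted p = 0.065), and their median was 1.80 in HEN replicate 3, where HBM, a globin gene, was at 496 FPKM against 35.3 to 97.9 FPKM in the other libraries. Without HEN replicates 2 and 3 the erythrocyte list had a median of -0.45 and its direction in camera was downward, the reverse of that over all libraries. It passed as higher without HEN replicate 1 (median 0.89, adjusted p = 0.00925), HEN replicate 2 (0.71, 0.0361) or LEN replicate 3 (0.56, 0.0183) and with arrayWeights (1.05, 0.00393). Without HEN replicate 3 its median was negative (-0.049, adjusted p = 0.979).

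Oocyte and germ cell markers had the lowest list median, at -3.09 over 24 genes. ZP4, a component of the egg coat, was at 74.2, 0.098 and 0.608 FPKM in HEN replicates 1, 2 and 3 and at 102, 92.4 and 275 FPKM in LEN replicates 1, 2 and 3. DDX4, the germ cell helicase, was at 14.3, 0 and 0.208 FPKM in HEN and 27.8, 16.1 and 29.4 FPKM in LEN. The list shifted downward in camera (adjusted p = 5.91e-04), with adjusted p = 0.659 with an estimated correlation. No member passed over all genes and 16 passed as lower adjusted over the list alone. The list median was -0.41 in HEN replicate 1, against -4.28 and -4.30 in replicates 2 and 3 and -0.54 to 0.35 in LEN. Without HEN replicate 1, 19 members passed as lower and 1 as higher. Without HEN replicates 2 and 3 the list's direction in camera was still downward. Its median there was -0.41, which lay above that of LEN replicate 2 (-0.54). Cell cycle genes moved in the same libraries (30 genes, median -1.94, camera adjusted p = 3.46e-04), with adjusted p = 0.659 with an estimated correlation and 0 members passed adjusted over the list alone. Their median was 0.03 in HEN replicate 1 and -3.61 and -2.46 in replicates 2 and 3, and 25 of 30 passed as lower without HEN replicate 1. The cell cycle list's median was -3.02 without HEN replicate 1 and -1.24 without HEN replicate 2. The spindle gene TPX2 was at 41.8, 1.09 and 4.26 FPKM in HEN and 70.7, 46.3 and 113 FPKM in LEN. Ciliated cell markers (15 genes, median -1.13) also shifted downward (camera adjusted p = 0.00918), with adjusted p = 0.659 with an estimated correlation and 0 members passed adjusted over the list alone. Their call and that of the cell cycle list were lost without HEN replicates 2 and 3 (medians -0.25 and 0.025, adjusted p = 0.702 and 0.48). The ciliated cell list also lost its call with a filter at a mean of 5 FPKM, where its median was larger (-1.85, adjusted p = 0.125), and with no filter (median -0.72, adjusted p = 0.0571). Its median was -1.96 and -1.99 with pseudocounts of 0.1 and 0.01 and -0.68 after quantile normalization.

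Hormone production genes varied between the HEN libraries. The 17 steroidogenesis genes had a median of -0.87, which did not pass relative to all other genes (camera adjusted p = 0.703), and list medians of 0.09 in HEN replicate 1 and -1.06 and -0.97 in replicates 2 and 3. Their median was -0.49 without HEN replicate 3, -0.40 with no filter and -0.50 after quantile normalization. CYP19A1, which makes oestrogens, was at 46.7, 2.61 and 5.69 FPKM in HEN and 40.7, 70.7 and 41.5 FPKM in LEN. Without HEN replicate 1, 10 of the 17 passed as lower and 3 as higher. Cholesterol synthesis and uptake genes (22 genes, median -0.92) did not pass in the values as deposited (adjusted p = 0.15) and passed as lower after upper quartile, trimmed mean or quantile scaling (medians -0.65, -0.68 and -0.63, adjusted p = 0.0462, 0.0493 and 0.0258). They also passed as lower without HEN replicate 1 (median -1.47, adjusted p = 0.0219) and with arrayWeights (median -1.50, adjusted p = 0.0439), while without HEN replicates 2 and 3 the median was -0.018. The sterol enzyme genes LSS and NSDHL differed by -2.37 ± 0.86 and -2.89 ± 1.10 (SE). Granulosa cell markers had a median of 0.08, a mean of -0.01 and an adjusted p of 0.55, with WT1 at -1.12 ± 0.37 (SE). The granulosa median changed sign between alternatives, at 0.17 without HEN replicate 1, -0.42 without HEN replicate 2, -0.043 without LEN replicate 1 and 0.45 after quantile normalization. Gonadotropin and steroid hormone receptors (20 genes, median 0.11, adjusted p = 0.164) and WNT signalling genes (32 genes, median -0.33, adjusted p = 0.986) did not pass in the values as deposited. The WNT median was -0.21 without HEN replicate 3, -0.20 without LEN replicate 1 and -0.70 with arrayWeights. The receptor list passed as higher without LEN replicate 1 (median 0.27, adjusted p = 0.0496). Its median was negative without HEN replicate 1 (-0.053), HEN replicate 3 (-0.003) or LEN replicate 3 (-0.205, adjusted p = 0.588), with no filter (-0.068) and with arrayWeights (-0.19). TGF-beta, BMP and activin genes shifted upward in camera (29 genes, median 0.28, adjusted p = 0.0149), with adjusted p = 0.453 with an estimated correlation and 0 members passed adjusted over the list alone. BMP2, BMP7 and BMP15 in that list differed by -1.41 ± 0.44, -1.57 ± 0.53 and -3.19 ± 1.10 (SE), and the receptor TGFBR2 by 1.17 ± 0.40 (SE). The call of the TGF-beta list was lost without HEN replicates 2 and 3 (median 0.055, adjusted p = 0.702), without LEN replicate 3 (median 0.11, adjusted p = 0.058) and with a filter at a mean of 5 FPKM (median 0.24, adjusted p = 0.0501). Its median was 0.17 without HEN replicate 3, 0.15 with arrayWeights and 0.54, 0.51 and 0.56 after scaling by the upper quartile, trimmed means or quantiles.

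Among general cell functions, 52 of 56 ribosomal protein genes had a higher mean in HEN. The list shifted upward in camera (median 0.30, adjusted p = 1.4e-09), with adjusted p = 0.659 with an estimated correlation, but after quantile normalization its direction was downward (median -0.04, adjusted p = 0.532). The ribosomal median was 0.14 without HEN replicate 2, 0.58 after upper quartile scaling and 0.55 with trimmed means. RPL29 differed by 0.96 ± 0.30 and RPS23 by 0.88 ± 0.28 (SE), and no member passed adjusted over the list alone. Apoptosis and autophagy genes shifted upward (34 genes, median 0.20, camera adjusted p = 0.00141), with adjusted p = 0.453 with an estimated correlation and 0 members passed adjusted over the list alone. In that list the lysosomal protease CTSB differed by 1.51 ± 0.49 and the autophagy receptor SQSTM1 by -0.57 ± 0.20 (SE). Without HEN replicates 2 and 3 the ribosomal and apoptosis lists had medians of 0.083 and 0.11 (adjusted p = 0.0547 and 0.175). The apoptosis median was 0.39 without HEN replicate 1, 0.33 without LEN replicate 2, 0.41 with arrayWeights and 0.49, 0.46 and 0.43 after scaling by the upper quartile, trimmed means or quantiles. Oxidative phosphorylation genes (29 genes, median -0.14, adjusted p = 0.888) and immediate early and heat shock genes (23 genes, median -0.14, adjusted p = 0.95) did not pass, and both medians were positive after upper quartile, trimmed mean or quantile scaling. Leaving out 1 library moved the medians over -0.27 to 0.006 (highest without LEN replicate 3, adjusted p = 0.0501) and -0.26 to -0.031. The chaperone gene HSP90AA1 differed by -1.01 ± 0.30 (SE).

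Markers of other tissues did not pass in camera. These were oviduct epithelium (8 genes, median -1.17, adjusted p = 0.651), liver and yolk proteins (5 genes, median -0.73, adjusted p = 0.889), adrenal and chromaffin cells (7 genes, median -0.36, adjusted p = 0.419), skeletal muscle (7 genes, median -0.94, adjusted p = 0.651) and adipocytes (12 genes, median -0.17, adjusted p = 0.672). For the liver, adipocyte and oxidative phosphorylation lists the camera direction was upward although the median and mean were negative, since camera compares a list with all other genes. The adipocyte median was positive after upper quartile, trimmed mean or quantile scaling (0.10, 0.07 and 0.11), as were the adrenal and WNT medians after quantile normalization (0.33 and 0.09) and the oviduct median with a filter at a mean of 5 FPKM (0.16, camera direction upward, adjusted p = 0.632). Without HEN replicates 2 and 3 the liver, skeletal muscle and WNT medians were positive (0.16, 0.26 and 0.07). Leaving out 1 library moved the liver median over -1.18 to -0.31, the skeletal muscle median over -1.46 to -0.47 and the adipocyte median over -0.34 to -0.047. The epithelial genes EPCAM and KRT7 differed by -3.20 ± 1.18 and 1.33 ± 0.36 (SE), and EPCAM was at 97.2 FPKM in HEN replicate 1 against 3.07 and 2.96 FPKM in replicates 2 and 3. The adipocyte gene ADIPOQ differed by 0.58 ± 0.26 (SE).

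Over all 28 lists, camera called 14 with the preset correlation, 11 upward and 3 downward, and 0 with an estimated correlation, where 2 had an unadjusted p under 0.05. fry, limma's rotation test of each list by itself, called 0 in its test of 1 direction, also with 2 at an unadjusted p under 0.05. Its mixed test, for changes in either direction and added after the data were seen, called 1, the interferon list (adjusted p = 0.00403), with 4 at an unadjusted p under 0.05. Without HEN replicates 2 and 3 camera called 6 lists, which describes 1 HEN duck. The 4 upward were the focal adhesion, interferon, theca and stroma, and smooth muscle lists. The 2 downward were the oocyte and erythrocyte lists. For 6 of 28 lists (21.4%) the medians of the groups did not overlap. Chance gives 10% on average over splits only where both groups are measured alike, but these medians are relative to the LEN mean. Lists also share members and vary together, so the share does not by itself show a group difference. HEN lay above LEN for the focal adhesion, apoptosis, interferon, theca and stroma, and smooth muscle lists and below for the ciliated cell list. The separation was narrow for the ciliated list (HEN replicate 1 at -0.252, LEN replicate 2 at -0.243) and the apoptosis list (0.106 and 0.088). Each LEN library is set against a mean that includes itself, which narrows the LEN range and favours separation. With each LEN library set against the other 2, the interferon list's LEN medians were -0.081 to -0.036, still below HEN. For the other lists named here this was not computed, so their separations are uncertain.

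**Figure D3:**
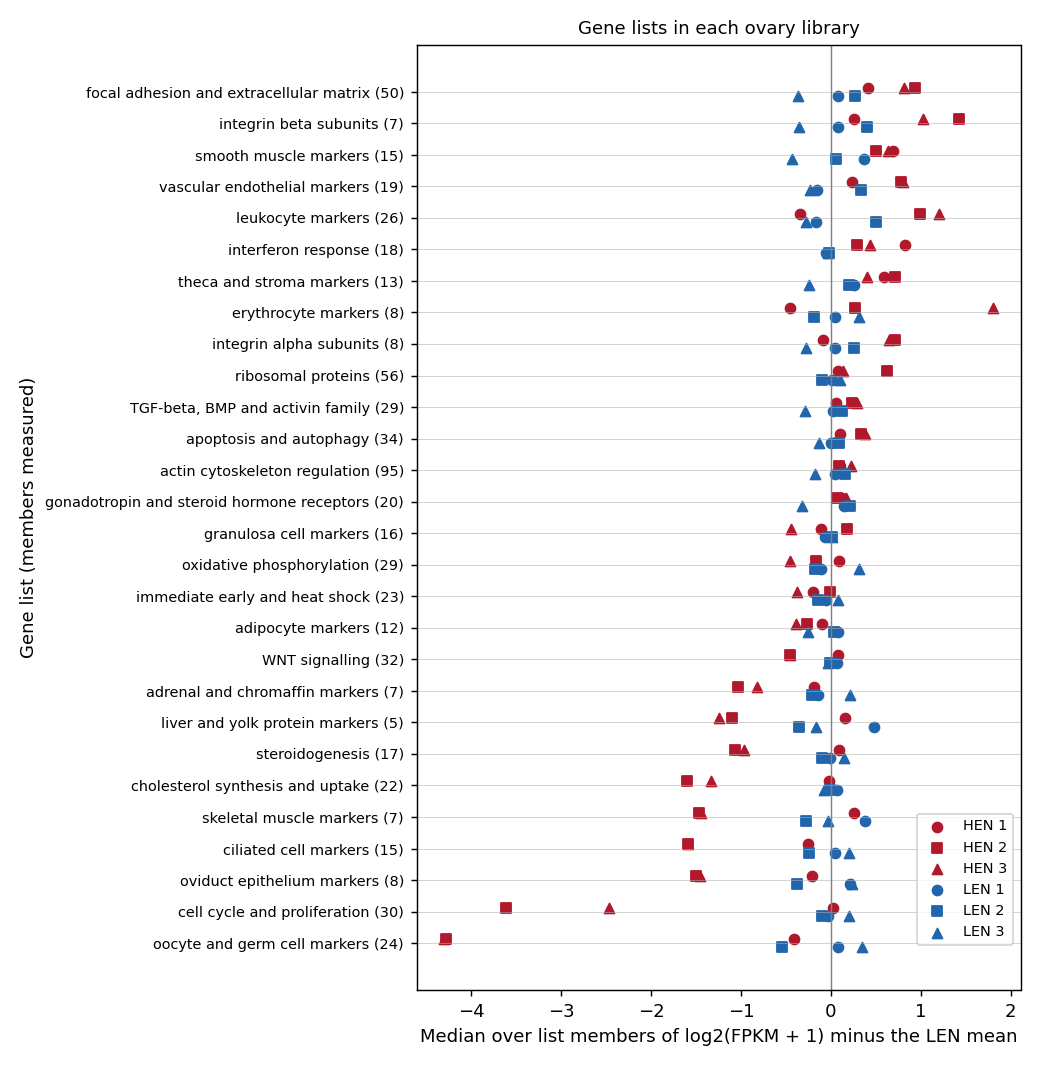
Median over the members of each of 28 gene lists of log2(FPKM + 1) minus the LEN mean, with 1 point per ovary library and the number of measured members in brackets. HEN replicates 2 and 3 lie at -4.28 and -4.30 for oocyte markers where HEN replicate 1 lies at -0.41, whereas for the interferon list HEN replicate 1 is highest at 0.83.

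The smallest unadjusted p values belonged to unnamed transcripts, singled out after their values were seen. ENSAPLT00000001063 (scaffold KB743370.1 from 10513 to 10581, annotated as protein-coding) was at 0 FPKM in all 3 HEN libraries and at 39.9, 13.9 and 34.8 FPKM in LEN replicates 1, 2 and 3, or 53, 19 and 44 fragments. Against a floor of 3 fragments per library it was at least 12.7-fold lower in HEN, a bound that covers counting error only. Its adjusted p in limma was 0.11. ENSAPLT00000004567 (scaffold KB818638.1 from 187 to 781) was at 0.472 ± 0.362 FPKM in HEN and 21.8 ± 7.74 FPKM in LEN (SD, n = 3 per group), a difference of -3.92 ± 0.37 (SE), also with an adjusted p of 0.11.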

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

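Leaving out HEN replicates 2 and 3 together, using protein-coding rows alone and fry's mixed test were chosen after the data were seen, and the other alternatives before. In limma, the count of transcripts past the threshold was 0 in the values as reported and 0 in most alternatives, with 2929 at an unadjusted p under 0.05. It was 1 with a pseudocount of 0.1, 1 after scaling to TPM and 1 without HEN replicates 2 and 3, 7922 with arrayWeights and 0 to 6501 on leaving out 1 library, with 6501 without HEN replicate 1 and 0 without each of the others. The transcript called with a pseudocount of 0.1 and after scaling was ENSAPLT00000001063 in both, and without HEN replicates 2 and 3 it was the pseudogene transcript ENSAPLT00000007367. Without HEN replicates 2 and 3 the lone HEN library is assumed to vary like LEN, so calls in that setting describe 1 duck. An unadjusted p under 0.05 with a log2 difference of at least 1 held for 2179 transcripts.

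The integrin beta list kept its upward direction with an adjusted p of 0.0692 after upper quartile scaling (median 1.15, from 0.87), 0.0631 with trimmed means (1.13), 0.0749 with quantiles (1.14), 0.1 without HEN replicates 2 and 3 (0.25), 0.453 with an estimated correlation and 0.259 with fry. Leaving out 1 library gave 0.00842 to 0.0243 for integrin beta and 1.4e-05 to 8.19e-04 for actin. The actin list had adjusted p of 0.0544, 0.453 and 0.35 without HEN replicates 2 and 3, with an estimated correlation and with fry. The number of lists called was 14 as reported, 6 without HEN replicates 2 and 3, 0 with an estimated correlation, 0 with fry's test of 1 direction, 1 with fry's mixed test, 12 (of 25 lists) with a mean of at least 5 FPKM, 13 with no filter, 13 after quantile normalization, 17 with arrayWeights and 14 to 17 on leaving out 1 library. fry's test of 1 direction and the estimated correlation use the spread of the libraries or the correlation between members in place of the preset 0.01, and the cause of the other changes was not tested.

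Of 128 named genes, 113 passed without HEN replicate 1 and all but 5 with arrayWeights, none with a reversed direction. Of all 13328 transcripts, 6501 and 7922 passed in those settings. Most named genes were picked for a small unadjusted p in these same libraries, so these counts are not separate support for them. Reversed were APOA1 (-0.10) and SLC18A2 (0.33) after quantile normalization, from 0.94 and -0.36. Leaving out 1 library moved SPTB over -0.022 to 1.05 and HBM over -0.071 to 1.79, reversing both without HEN replicate 3, from 0.62 and 0.94. The cause was not tested for APOA1 and SLC18A2. The deviations of libraries with the same replicate number correlated at 0.02, 0.38 and -0.42. These values largely follow the distance of HEN replicate 1 from the other HEN libraries. LEN replicate 2, for example, correlated at -0.49 with HEN replicate 1 and at 0.38 and 0.46 with replicates 2 and 3. Whether the numbers pair the ducks therefore cannot be told. With the replicate block, 0 transcripts passed (2800 at an unadjusted p under 0.05), 15 lists were called, the erythrocyte list being the addition (upward, adjusted p = 0.0201), and the integrin beta and actin lists had adjusted p of 0.00583 and 4.73e-05. Depth was similar in all libraries, at 18213744 to 19831761 fragments, and limits values near 0.16 FPKM on 1 kb.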

Other observations

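The tests of explanations and the counts over other splits were chosen after the results were seen, while the tests of the real split and of the lists without HEN replicate 1 were planned, and the genes of the next paragraph were singled out by their weight on the leading principal component.

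Some genes with large weights on that component had high levels in HEN replicates 2 and 3, without a test of any gene group. The collagenase gene MMP13 was at 1338 and 570.4 FPKM in HEN replicates 2 and 3, against 1.08 FPKM in HEN replicate 1 and 1.79 to 9.29 FPKM in LEN. MMP9, a gelatinase, was at 502 and 362 FPKM against 6.51 FPKM in HEN replicate 1 and 5.18, 43.1 and 5.20 FPKM in LEN replicates 1, 2 and 3. The prostaglandin synthase PTGS2 was at 141 and 160.5 FPKM against 8.64 FPKM in HEN replicate 1 and 4.26 to 7.08 FPKM in LEN. MMP7 was at 736 FPKM in HEN replicate 2 but 4.50 FPKM in HEN replicate 3. The oxidase gene DUOX2 with its maturation factor DUOXA2, the chemokine IL8 and the WNT-binding protein SFRP4 lay on the same side. At the other end, NRN1 was at 0.456 and 0.235 FPKM in HEN replicates 2 and 3 against 606 FPKM in HEN replicate 1 and 472 to 949 FPKM in LEN, and CYP17A1, an enzyme of androgen synthesis, was at 0.095 and 0.146 FPKM against 239.6 FPKM in HEN replicate 1 and 33.5 to 520.5 FPKM in LEN. The first component held 84.1% of the variance and separated HEN replicates 2 and 3 (109 and 104) from HEN replicate 1 (-44.3) and the LEN libraries (-35.5 to -77.6).

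HEN replicates 2 and 3 stood apart from the other 4 libraries. The highest correlation of a LEN library with HEN replicate 2 or 3 was 0.779, and the lowest between LEN libraries was 0.933. This argues against an exchange of HEN replicate 1 with a LEN library only if every HEN ovary should resemble replicates 2 and 3. Otherwise an exchange among the other 4 libraries cannot be told, since these correlated at 0.933 or more with each other. Whether a lower share of oocytes alone would suffice was not decided. Steroidogenesis members lay 2.53 log2 units below vascular endothelial members in HEN replicate 2 (difference -2.53, permutation p = 0.00012 over genes). In HEN replicate 3 they differed by -2.37 (permutation p = 8e-05), over 17 and 19 genes. These lists were paired after their medians were seen, and the permutation treats genes of 1 duck as replicates. The values show only that these lists did not move alike. Granulosa medians were 0.18 and -0.45 in HEN replicates 2 and 3. A wrong label on HEN replicate 1 alone cannot be told apart from a real difference between ducks, since its lowest correlation with a LEN library, 0.933, equalled the lowest between LEN libraries. With the labels as given, the egg number group alone cannot explain why HEN replicates 2 and 3 stood apart, since replicate 1 shares it. Egg numbers of single ducks, or a tissue piece with fewer small follicles and more stroma, may explain it, and neither was tested. For stroma the lists were mixed. Theca and stroma medians were 0.585, 0.708 and 0.406 in HEN replicates 1, 2 and 3 and smooth muscle medians 0.69, 0.5 and 0.63. Endothelial medians were 0.231, 0.783 and 0.806.

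The upward shift of the integrin beta list may be carried by HEN replicates 2 and 3. Its median in HEN replicate 1 was 0.25 above the LEN mean, within the range of the LEN libraries (-0.36 to 0.40). Whether high egg number or the makeup of those tissue pieces accounts for the shift stays open.

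The upward shift of the interferon list is less likely to rest on HEN replicates 2 and 3 alone, and without HEN replicate 1 its adjusted p was 0.0465. Its median in HEN replicate 1 was 0.83 (bootstrap interval 0.27 to 1.28), above all LEN libraries (-0.054 to -0.024), and each LEN library set against the mean of the other 2 LEN libraries lay at -0.081 to -0.036. The leukocyte list's median in HEN replicate 1 was -0.34 (bootstrap interval over members -0.55 to -0.02), so the list as a whole was not raised there. Its members pointed both ways, however. MARCO, C1QB and CSF3R were at 53.9, 53.3 and 4.42 FPKM in HEN replicate 1, above all LEN libraries, whereas PAX5 was at 0 FPKM. A larger share of some kinds of leukocytes in HEN replicate 1 therefore stays open. A larger share of leukocytes in HEN replicates 2 and 3 cannot be told apart from another source, because the leukocyte list was also high there (0.99 and 1.20). An immune response in HEN replicate 1 remains a hypothesis from 1 duck, and egg number was not separated from it.

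The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. For genes past the threshold, 10 of the 10 splits gave at least the real 0 (highest other 0), which any split must do, so that this count decides nothing. The real split had 2929 and the highest other 4145 at an unadjusted p under 0.05. That other split set HEN replicates 2 and 3 with LEN replicate 2 against the rest, which points to a structure of the samples. For lists, 2 of the 10 splits gave as many as the real 14, and the highest other was 16. The integrin beta list had an adjusted p as small in 1 split, the real one (0.012, smallest other 0.0216), as did the actin list in 1 split (4.18e-05, smallest other 7.91e-05).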
